A study of Homo sapiens with 15 samples.

How the data were processed

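RNA sequencing of tumours grown from MCF7 cells was analysed from the table of gene counts that the authors deposited. MCF7 is an established human breast cancer line that carries the oestrogen receptor. Per the labels' protocols, the cells were xenografted in mice, treatment began 2 weeks later and lasted 4 weeks, total RNA was extracted with a silica-column kit, and polyadenylated RNA was sequenced on an Illumina instrument. The labels put the 15 libraries in 4 arms. The arms were free feeding (control, 3 libraries), tamoxifen at 30 mg/kg on 5 days a week (3 libraries), only water for 48 h a week (fasting, 3 libraries) and both treatments (combination, 6 libraries).

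The deposited values were raw counts per gene, with 1 column per library and no normalization. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.5.3 and the genome build hg38 (GRCh38). The options used, the annotation release, the strand setting and the handling of mouse reads were not given in the sources used here. Reads of host cells that match the human genome could therefore have entered the counts, and genes that overlap, lie antisense to each other or are near-identical copies can share reads. The table had 60675 lines, of which 60674 named a gene and 1 had no name. The unnamed line held 1 count over all libraries and was left out, and 28048 genes had no count in any library. The table paired each Ensembl identifier with a symbol and with coordinates, which are those printed here. All 15 library columns matched a sample by title, and 0 columns belonged to other samples.

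Total counts per library ran from 9894813 to 14958166. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by arm, which left 15834 genes, and libraries were scaled with the trimmed mean of M values (TMM). A quasi-likelihood model with robust shrinkage was fitted to all 15 libraries with a mean per arm and no other term, so that the arms shared an estimate of the spread. F tests gave 6 comparisons, namely tamoxifen, fasting and the combination each against control, the combination against tamoxifen, the combination against fasting, and the interaction. The interaction is the difference between the combination and tamoxifen minus the difference between fasting and control. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, with a threshold of 0.05 and no minimum fold change. Unless another test is named, an adjusted p of a gene is from this edgeR quasi-likelihood test. The SE of a log2 fold change was computed as its absolute value divided by the square root of the F statistic. It is therefore an approximation and not an estimate that the fit gave. Levels are TMM-scaled counts divided by library size (CPM), and log2 CPM used a prior count of 2.

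Before the data were examined, 31 gene lists were fixed, of which 19 named pathways, 10 cell types and 2 RNA quality. They were tested with camera in limma 3.58.1 on voom log2 CPM, with a preset correlation between genes of 0.01. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the lists of a comparison. Lists with fewer than 3 measured members were not tested. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Some genes stand in more than 1 list, for example 8 of the glucocorticoid receptor targets and 5 of the oestrogen receptor targets.

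The genes named below were also chosen by a rule set before the data were examined. It took, per comparison, up to 6 genes that rose and up to 6 that fell with the largest change among called genes with an average log2 CPM of at least 1 and no overlap between the arms. It added up to 3 called members per list with the smallest p, and a panel of 14 genes reported whether or not they passed. Where 5 or fewer members of a list passed in a direction they may all be named, and those outside the rule were chosen after their values were seen. A fold change against an arm with no count was computed against 3 counts over the arm and is a lower limit. With 1 to 3 counts the ratio is given with an exact 95% interval. These limits and intervals cover counting error only, since the reads carried no reported molecular identifiers.

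The fit was tested on simulated counts with known fold changes added. They were drawn gene by gene from the mean over all 15 libraries, the real library sizes and the estimated spread of each gene. The simulation holds no structure among the libraries of an arm, so the shares below describe a cleaner setting than the data. In the simulated comparison of tamoxifen with control over 15616 genes, 26.9% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 90.9% of those changed 4-fold were called. For the combination against control, over 15610 genes, the shares were 41.8%, 65.7% and 98.5%. For the interaction, over 15610 genes, they were 10.4%, 46.3% and 80.3%. The unchanged genes called numbered 11, 5 and 4. In each of these 3 comparisons a simulated list of 25 genes raised 1.5-fold was called, and 0 of 20 unchanged lists were. Since the simulated genes were independent, that result does not test the preset correlation for lists whose genes vary together.

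Correlations between comparisons were set against 20 simulations in which no arm differed and each gene was drawn independently. The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom without and with library weights, DESeq2 size factors and upper-quartile scaling in edgeR, no low-count filter, and a stricter filter of at least 1 CPM in 3 libraries and 50 counts in total. The others were fits of the compared arms alone, of combination replicates 1 to 3, with the replicate number as a block, and without each library in turn. A pair of fits, without combination libraries 1 and 2 and without 1, 2 and 5, was added after the data had been seen.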

Results

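Gene expression was measured by RNA sequencing in 15 libraries from MCF7 tumours grown in mice, in 4 arms. Tamoxifen is a drug that blocks the oestrogen receptor in breast tissue, and the series set out to learn how weekly fasting acts on such treatment, with an interest in glucocorticoid signalling. Total counts ran from 11985830 to 13239913 in the 3 control libraries, from 12354895 to 13523033 in the 3 tamoxifen libraries, from 12221023 to 14958166 in the 3 fasting libraries, and from 9894813 to 13261758 in the 6 combination libraries. Nothing in the labels says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. All pairs of libraries within an arm differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.49. That lowest value was for combination libraries 3 and 4, against 11.7 to 53.4 in the other pairs of that arm. In the other arms it was at least 7.45. Why libraries 3 and 4 lie so close is not in the labels, and each library was counted once.

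The first principal component held 40.5% of the variance and the second 16.1%. On the first, the controls lay between -49.09 and -42.96 and the tamoxifen libraries between -7.55 and -2.82. Fasting libraries 1 and 2 lay at -20.09 and -12.72, and fasting library 3 lay at -40.02, near the controls. Combination libraries 1 and 2 lay at 61.02 and 58.01, libraries 3, 4 and 6 between 31.47 and 34.76, and library 5 at 12.41. The mitosis genes separated combination libraries 1 and 2 from all others, with a mean log2 deviation of -0.761 and -1.24, against -0.03 to 0.307 in the other 13.

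**Figure D1:**
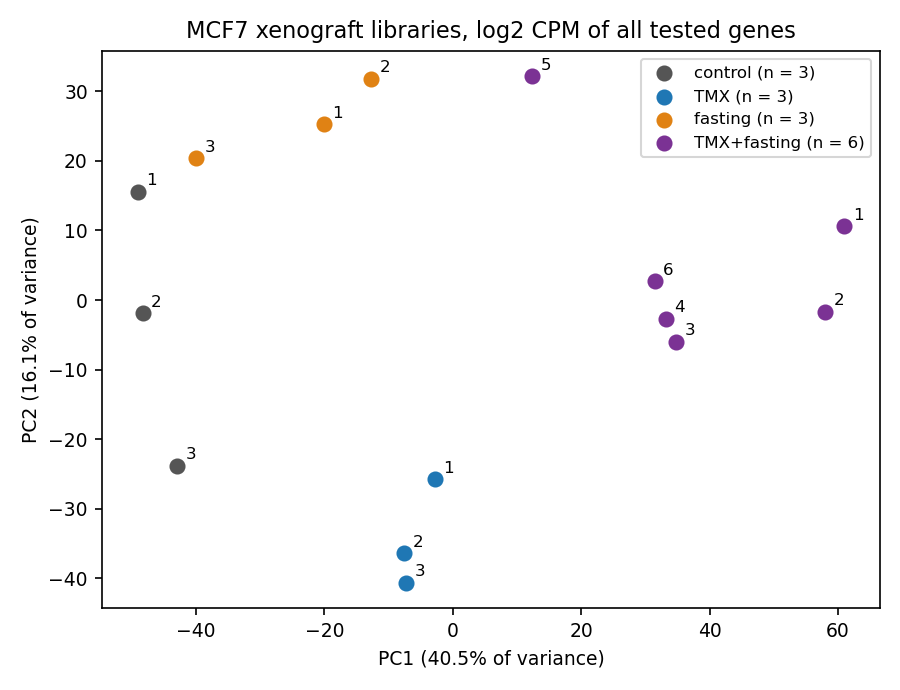
Principal components of log2 CPM, first component on the x axis and second on the y axis, with a point per library coloured by arm. Controls lie at -49.09 to -42.96 on the first component and the 6 combination libraries at 12.41 to 61.02.

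The comparison of tamoxifen with control asked what the drug alone did to the tumours. Some oestrogen receptor targets fell, and a few genes that were almost silent in the controls, such as SIM1, rose. NPY1R, a neuropeptide Y receptor gene (ENSG00000164128, chromosome 4, 163323962 to 163344832, GRCh38), which overlaps NPY5R, was 13.9-fold lower, at 28.8 ± 8.11 CPM with tamoxifen (SD, n = 3; log2 fold change -3.80 ± 0.41 SE, edgeR adjusted p = 0.000341). SIM1, which encodes a transcription factor (chromosome 6, 100385009 to 100464921), rose from 3 counts over the controls to 689, a ratio of 221 (95% interval 75.4 to 1080). IGHG4, an immunoglobulin heavy chain gene (chromosome 14, 105620506 to 105626066), rose from 0.575 ± 0.0657 to 18.7 ± 7.06 CPM (SD, n = 3 each; log2 fold change 5.00 ± 0.47 SE, edgeR adjusted p = 7.92e-05). In all, 493 of 15834 genes were called, 230 higher and 263 lower, and 283 of them changed over 2-fold.

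Of 38 measured oestrogen receptor targets, 12 fell and 3 rose with tamoxifen (18 and 7 adjusted over the list alone). Their median log2 fold change was -0.71 (camera adjusted p = 2.64e-06, adjusted p = 0.638 with an estimated correlation). SGK3, a kinase gene, fell by 2.97 ± 0.29 SE on the log2 scale, PKIB by 1.98 ± 0.20 and SIAH2 by 1.19 ± 0.13. RET, SLC9A3R1 and AGR2 rose, by 1.11, 0.55 and 1.01. Transcripts of the receptor itself did not pass, with ESR1 at a log2 fold change of -0.17 ± 0.18 SE, and neither did GREB1 at -0.86 ± 0.49 or TFF1 at -0.06 ± 0.20. The progesterone receptor gene PGR went from 213 ± 72.2 to 49.9 ± 20.01 CPM (SD, n = 3 each; log2 fold change -2.09 ± 0.51 SE, edgeR adjusted p = 0.0442). The androgen receptor gene AR rose by 0.78 ± 0.19. KRT8 fell by 0.65 ± 0.13 and KRT18 by 0.60 ± 0.14, and the last pair overlap on the genome. The rest of the 15 luminal epithelium markers did not pass (3 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.466).

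Of 26 glucocorticoid receptor targets, 4 fell and 0 rose (5 and 0 adjusted over the list alone; camera adjusted p = 0.0849, adjusted p = 0.638 with an estimated correlation). SGK1, a kinase gene induced by glucocorticoids (chromosome 6, 134169246 to 134318112), went from 25.6 ± 11.4 to 4.16 ± 1.53 CPM (SD, n = 3 each; log2 fold change -2.62 ± 0.39 SE, edgeR adjusted p = 0.00334). FKBP5 fell by 1.15 ± 0.28 and TIPARP by 0.59, and BIRC3 fell as well. Among the immediate early genes, IER3 rose by 1.96 ± 0.20 and EGR3 fell by 2.14 ± 0.36. INSR, the insulin receptor gene, fell by 0.97 ± 0.14, and ELF5, a transcription factor gene of the mammary epithelium, rose by 1.58 ± 0.28. Interferon-stimulated genes had a median log2 fold change of -0.83, with 1 of 24, OAS1, past the threshold (19 lower adjusted over the list alone; camera adjusted p = 8.48e-10, adjusted p = 0.638 with an estimated correlation). That list varied among the controls, from a mean log2 deviation of 0.73 in control library 1 to -0.709 in control library 3. Without control library 1 the median of the list interferon response in TMX vs control was -0.505. The myeloid list moved the same way, at 1.05, 0.875 and -0.443 in the controls and -1.13 to -0.569 with tamoxifen (0 of 4 called, 2 lower adjusted over the list alone; median -1.28, camera adjusted p = 0.0849). Its member CD74, chosen after its values were seen, had a log2 fold change of -3.31 ± 0.84 SE (edgeR adjusted p = 0.052). Fatty acid synthesis genes had a median of -0.35 with 0 of 13 past the threshold (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.638 with an estimated correlation). That call was lost without control library 2 (median -0.12).

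Of 31 named genes called with tamoxifen, 15 were called whichever library was left out, among them NPY1R, SIM1, IGHG4, SGK1, SGK3 and IER3, while PGR (10 libraries, -2.45 to -1.80), FKBP5 (9 libraries, -1.40 to -0.92), AR (4 libraries, 0.67 to 0.97), KRT8 and KRT18 (5 libraries each) and OAS1 (4 libraries, -1.02 to -0.66) were lost in at least 1 such fit. The count of 493 became 204 and 181 without control libraries 1 and 2, 218, 189 and 231 without tamoxifen libraries 1, 2 and 3, and 795 without combination library 5, and it was 858 with DESeq2, 1369 with quality weights and 791 from the libraries of the arms compared.

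The comparison of fasting with control asked what weekly food withdrawal alone did to the tumours. Some genes of cholesterol synthesis and of ribosome biogenesis fell, and a few genes that rise on insulin withdrawal rose. SCD, the enzyme that makes monounsaturated fatty acids (ENSG00000099194, chromosome 10, 100347233 to 100364826), went from 2163 ± 569 to 859.5 ± 68.4 CPM (SD, n = 3 each; log2 fold change -1.33 ± 0.15 SE, edgeR adjusted p = 0.00146). PSCA, a cell surface antigen gene (chromosome 8, 142670308 to 142682725), went from 4.03 ± 0.942 to 31.3 ± 20.1 CPM (SD, n = 3 each; log2 fold change 2.96 ± 0.50 SE, edgeR adjusted p = 0.0204). SOCS2, a brake on growth hormone signalling that overlaps its antisense gene SOCS2-AS1, rose by 2.54 ± 0.54, and EMP1 by 2.27 ± 0.55. In all, 360 of 15834 genes were called, 169 higher and 191 lower, and 80 of them changed over 2-fold.

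Of 24 cholesterol synthesis genes, 11 fell and 0 rose with fasting (18 and 0 adjusted over the list alone; median log2 fold change -0.41, camera adjusted p = 2.37e-12, adjusted p = 0.169 with an estimated correlation). DHCR7 was down by 0.77 ± 0.11 SE, STARD4 by 1.28 ± 0.23 and HMGCS1 by 0.48 ± 0.09. Of 20 ribosome biogenesis genes, 8 fell (17 adjusted over the list alone; median -0.55, camera adjusted p = 1.14e-14, adjusted p = 0.169 with an estimated correlation), among them RRS1 by 0.86 ± 0.14, NOLC1 by 0.74 ± 0.14 and DKC1 by 0.57 ± 0.11. DNA replication genes had 3 of 25 lower, GINS2, FEN1 and E2F1 (15 adjusted over the list alone; median -0.50, camera adjusted p = 2.37e-12, adjusted p = 0.276 with an estimated correlation). Hypoxia and glycolysis genes had 2 of 25 lower, VEGFA and PGAM1 (9 adjusted over the list alone; median -0.58, camera adjusted p = 1.24e-07, adjusted p = 0.321 with an estimated correlation). Control library 3 was highest on that list, at 0.884 against 0.26 and 0.081 in the other 2, and without it the median of the list hypoxia and glycolysis in fasting vs control was -0.28 (camera adjusted p = 0.00153). Fatty acid synthesis had SCD alone of 13 (3 adjusted over the list alone; camera adjusted p = 0.00108, adjusted p = 0.276 with an estimated correlation). Fasting library 3 stood apart on part of these lists. For DNA replication it had a mean log2 deviation of 0.173, against -0.356 and -0.397 in fasting libraries 1 and 2 and 0.287 to 0.399 in the controls. For ribosome biogenesis it was at 0.097, against -0.297 and -0.308 and 0.33 to 0.411 in the controls.

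Of 19 genes that rise on insulin withdrawal, 5 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.34, camera adjusted p = 2.40e-05, adjusted p = 0.169 with an estimated correlation), namely FBXO32 by 1.24 ± 0.21 SE, KLHL24 by 0.89 ± 0.15, BCL6 by 1.15 ± 0.25, PIK3IP1 by 0.94 and YPEL3 by 1.17. Of 26 glucocorticoid receptor targets, SGK1 and SCNN1A rose and 0 fell (7 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 0.000102, adjusted p = 0.169 with an estimated correlation). SGK1 reached 87.3 ± 15.5 CPM, against 25.6 ± 11.4 in control (SD, n = 3 each; log2 fold change 1.77 ± 0.34 SE, edgeR adjusted p = 0.0298). SCNN1A, an epithelial sodium channel gene that overlaps LTBR, rose by 1.46 ± 0.26. The panel genes of the same class did not pass. KLF9 had a log2 fold change of 1.01 ± 0.27 (edgeR adjusted p = 0.0617), ZBTB16 3.64 ± 1.03 (0.0793), TSC22D3 0.69 ± 0.22 (0.0991), FKBP5 0.88 ± 0.28 (0.101) and PER1 0.52 ± 0.25 (0.253). The receptor gene NR3C1 was at 223 ± 24.4 CPM against 173 ± 17.7 in control (SD, n = 3 each; edgeR adjusted p = 0.292).

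Another 10 lists with 0 or 1 called member were past the camera threshold with the preset correlation, and none with an estimated correlation (adjusted p of 0.169 or more). They were oestrogen receptor targets (0 of 38 called, 0 adjusted over the list alone, median -0.35, camera adjusted p = 0.000503, adjusted p = 0.321 with an estimated correlation), oxidative phosphorylation (0 of 31, median -0.17, camera adjusted p = 4.14e-05, adjusted p = 0.345 with an estimated correlation) and progesterone receptor targets (ELF5 higher of 12, median 0.43, camera adjusted p = 0.0128, adjusted p = 0.272 with an estimated correlation). On the oestrogen receptor targets fasting library 3 went the other way, at 0.577 and above the controls (0.447 to 0.509), against -0.073 and -0.19 in libraries 1 and 2. Their median was -0.21 without fasting library 1, -0.19 without library 2 and -0.60 without library 3. The ATF4 stress response had a median of -0.28, the unfolded protein response -0.17, ribosomal proteins -0.12, mitochondrially encoded transcripts -0.16 and keratinocyte genes -0.56, while histone transcripts were at 0.36 and interferon-stimulated genes at 0.15. The preset calls were lost for interferon-stimulated genes without control library 3, for mitochondrial transcripts without control library 1 or fasting library 2, and for histones without control library 3 or fasting library 3. They were also lost for progesterone receptor targets without fasting library 1, for ribosomal proteins without fasting library 2 and for the unfolded protein response in 8 such fits (-0.22 to -0.09). Mitosis genes had a median of -0.02 with 0 of 23 called (0 adjusted over the list alone; camera adjusted p = 0.911), where the mean of 0.04 and the test pointed up. MKI67 was at 465 ± 51.3 CPM against 424 ± 52.6 in control (SD, n = 3 each).

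Apart from SCD, every named gene called here was lost when fasting library 1 or fasting library 2 was left out, each of which brought the count of 360 to 2, and without fasting library 3, which lay near the controls, it was 1137. The count was 12, 8 and 44 without control libraries 1, 2 and 3, 86 without tamoxifen library 2, 169, 132 and 621 without combination libraries 3, 4 and 5, 1031 with DESeq2, 3765 with quality weights and 16 from the libraries of the arms compared, and the interferon median was -0.08 without control library 3.

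**Figure D2:**
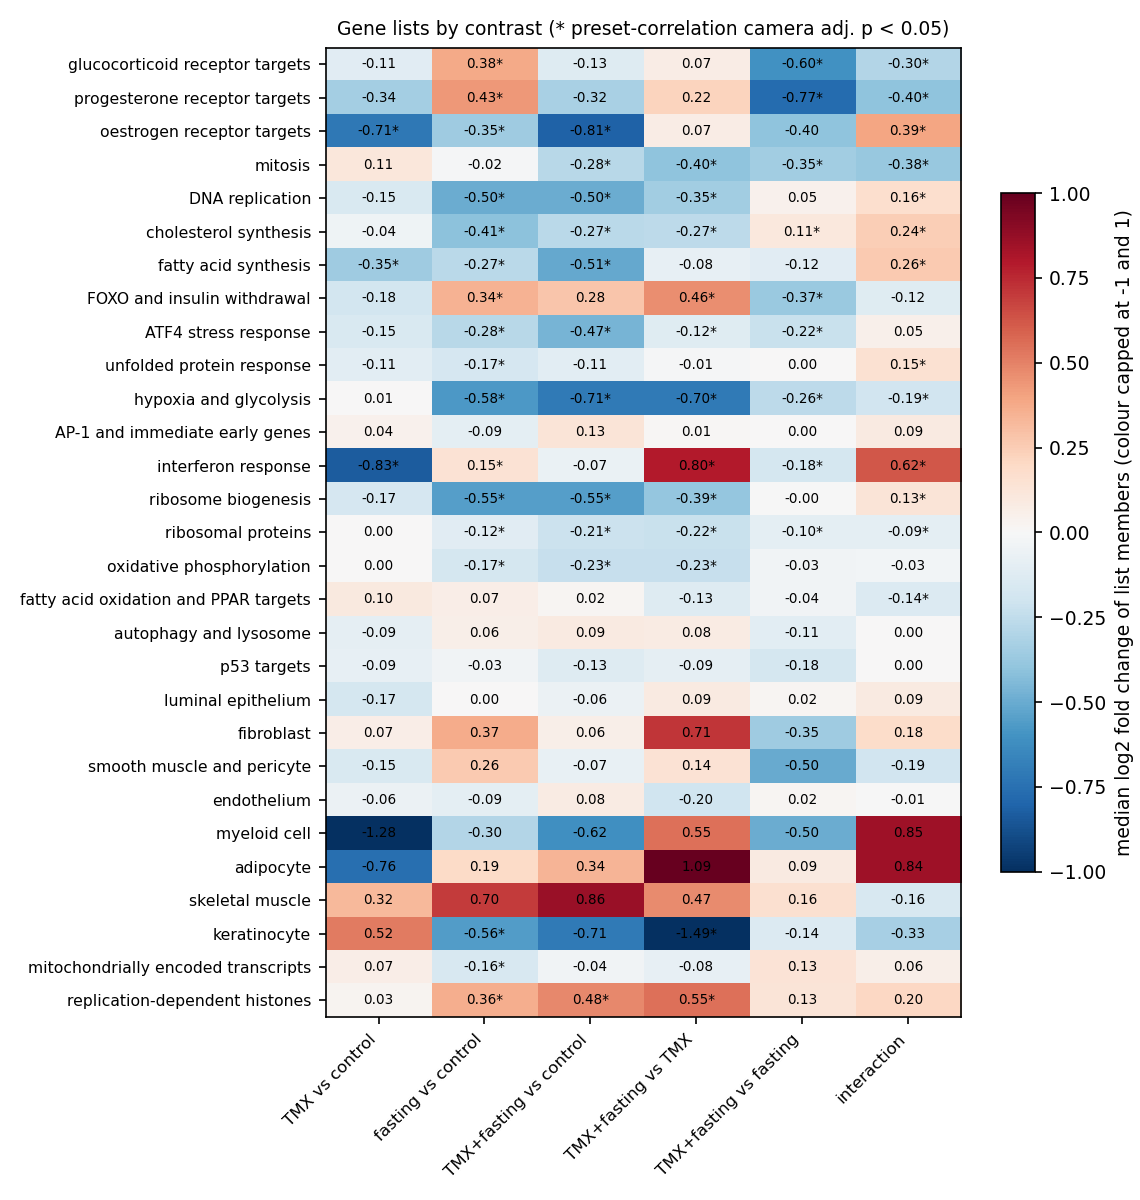
Heat map of the median log2 fold change of each gene list (vertical) in each of the 6 comparisons (horizontal), with colour capped at 1 in both directions. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation of 0.01, and hypoxia and glycolysis genes have the medians -0.58, -0.71 and -0.70 in the comparisons of fasting with control, the combination with control and the combination with tamoxifen.

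The comparison of the combination with control asked what both treatments did together. Among the genes that rose most were FOXJ1 and others near silent in the controls, and among those that fell most were IL20, IL24 and AREG. FOXJ1, the master transcription factor of motile cilia (ENSG00000129654, chromosome 17, 76136333 to 76141245), went from 0.386 ± 0.318 (n = 3) to 80.1 ± 31.4 CPM (SD, n = 6; log2 fold change 7.67 ± 0.63 SE, edgeR adjusted p = 1.35e-05). CDC20B, which lies in a locus active in multiciliated cells and overlaps GPX8, went from 0.75 ± 0.319 (n = 3) to 178 ± 86.5 CPM (SD, n = 6; log2 fold change 7.89 ± 0.81 SE, edgeR adjusted p = 4.59e-05). ZBBX was at least 85.7-fold higher and AL121956.7 at least 59.8-fold higher, while the ratio was 343 for MPPED1 (95% interval 94.8 to 2840) and 344 for SIM1 (118 to 1670). AREG, an epidermal growth factor family ligand (chromosome 4, 74445136 to 74455005), went from 134.6 ± 64.3 (n = 3) to 7.19 ± 4.06 CPM (SD, n = 6; log2 fold change -4.20 ± 0.63 SE, edgeR adjusted p = 0.000514). The cytokine genes IL20 and IL24 fell, with a log2 fold change of -6.74 ± 0.88 for IL20 and -5.72 ± 0.97 for IL24. IL24 and the unnamed transcript AC098935.1 overlap FCMR. In all, 4276 of 15834 genes were called, 2047 higher and 2229 lower, and 1265 of them changed over 2-fold.

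Of 25 hypoxia and glycolysis genes, 20 fell and 0 rose (20 and 1 adjusted over the list alone; median log2 fold change -0.71, camera adjusted p = 1.78e-08, adjusted p = 0.6 with an estimated correlation). Combination libraries 1, 2 and 5 were lowest on this list, at -0.68, -0.818 and -0.729, against -0.24 to 0.14 in the other 3 and 0.081 to 0.884 in the controls. Without them the median of the list hypoxia and glycolysis in TMX+fasting vs control was -0.60. VEGFA, the vascular growth factor, went from 147 ± 21.5 (n = 3) to 61.9 ± 8.69 CPM (SD, n = 6; log2 fold change -1.25 ± 0.12 SE, edgeR adjusted p = 1.48e-05), and lactate dehydrogenase LDHA fell by 1.18 ± 0.22. Of 20 ribosome biogenesis genes 16 fell (19 adjusted over the list alone; median -0.55, camera adjusted p = 2.35e-09, adjusted p = 0.6 with an estimated correlation). Of 25 DNA replication genes 14 fell (21 adjusted over the list alone; median -0.50, camera adjusted p = 3.49e-07, adjusted p = 0.6 with an estimated correlation). On that list combination library 2 was lowest, at -0.665, then library 1 at -0.229. The rest of the arm was at -0.124 to 0.06 and the controls at 0.287 to 0.399. In the lipid lists, 12 of 24 cholesterol synthesis genes fell and DHCR24 rose (14 and 1 adjusted over the list alone; camera adjusted p = 8.79e-05, adjusted p = 0.6 with an estimated correlation), and 7 of 13 fatty acid synthesis genes fell (7 adjusted over the list alone; camera adjusted p = 0.00522, adjusted p = 0.6 with an estimated correlation). DHCR7 was down by 0.77 ± 0.09, PCSK9 by 3.61 ± 0.51 and SCD by 1.16 ± 0.12. The ATF4 stress response had 11 of 26 genes lower and STC2 higher (13 and 1 adjusted over the list alone; camera adjusted p = 1.46e-05, adjusted p = 0.6 with an estimated correlation). Oxidative phosphorylation had 13 of 31 lower (13 adjusted over the list alone; camera adjusted p = 3.26e-05, adjusted p = 0.6 with an estimated correlation) and ribosomal proteins 9 of 32 (9 adjusted over the list alone; camera adjusted p = 1.42e-05, adjusted p = 0.736 with an estimated correlation).

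Of 38 oestrogen receptor targets, 18 fell and 7 rose (22 and 7 adjusted over the list alone; median -0.81, camera adjusted p = 0.00243, adjusted p = 0.6 with an estimated correlation). Without control library 1 the median of the list oestrogen receptor targets in TMX+fasting vs control was -0.53. PKIB fell by 1.67 ± 0.16 SE and SIAH2 by 0.85 ± 0.11, and SLC9A3R1 rose by 1.05 ± 0.13. The cell cycle gene CCND1 went from 860 ± 50.4 (n = 3) to 452 ± 100 CPM (SD, n = 6; log2 fold change -0.93 ± 0.16 SE, edgeR adjusted p = 0.00097). PGR fell by 1.65 ± 0.41 and AR rose by 1.05 ± 0.17, and GREB1 (edgeR adjusted p = 0.0565), TFF1 (0.0628) and ESR1 (0.175) did not pass. Of 26 glucocorticoid receptor targets, 9 fell and KLF9 rose (9 and 1 adjusted over the list alone; median -0.13, camera adjusted p = 0.294). Among them CRISPLD2 fell by 0.54 ± 0.12, TIPARP by 0.57 ± 0.13 and DDIT4, which stress and glucocorticoids induce, by 0.81 ± 0.19. FKBP5 was at 88.0 ± 26.0 CPM (n = 6) against 140 ± 49.1 in control (SD, n = 3; edgeR adjusted p = 0.0485) and KLF9 rose by 0.68 (edgeR adjusted p = 0.0473). In the insulin withdrawal list 7 genes rose and 5 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.345). TXNIP was up by 1.23 ± 0.19, RBL2 up by 0.96 ± 0.13 and IRS2 down by 1.34 ± 0.22. HMGCS2, the ketone-body synthase, rose by 4.55 ± 0.75. Mitosis genes had a median of -0.28 with 0 of 23 called (0 adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.784 with an estimated correlation), and combination libraries 1 and 2 were the lowest. Histone transcripts had H1-2, H2BC4 and H2BC21 higher of 8 (5 adjusted over the list alone; median 0.48, camera adjusted p = 0.0363, adjusted p = 0.736 with an estimated correlation), a call lost without control library 3 or combination library 2 or 6 (0.39 to 0.64).

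Of 85 named genes called, 60 were called whichever library was left out, while KRT6A and COL3A1 were lost without control library 2, PGR without control library 3, FKBP5 in 12 such fits (-0.93 to -0.44) and KLF9 in 11 (0.60 to 0.84), and the count of 4276 was 2749 without control library 2. The mitosis call was lost without combination library 1 (median -0.18) or library 2 (median -0.13), and without both as well (camera adjusted p = 0.78).

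**Figure D3:**
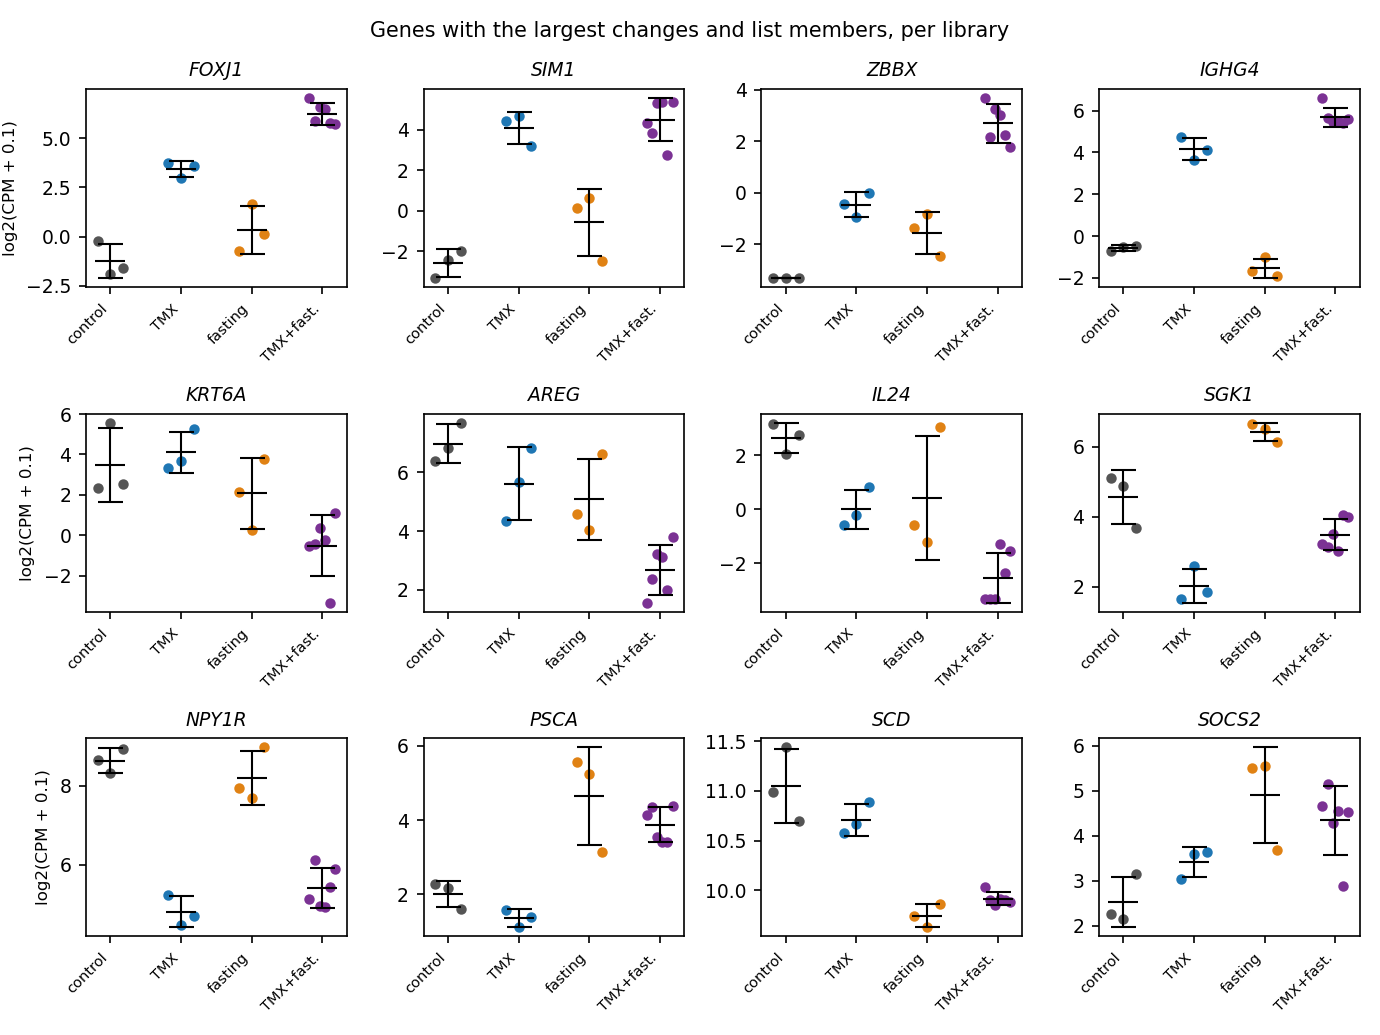
Log2(CPM + 0.1) of 12 named genes, 1 panel per gene, with a dot per library by arm and the mean ± SD per arm. FOXJ1 averages 0.386 CPM in control and 80.1 CPM in the combination arm, and SGK1 25.6 CPM in control, 4.16 with tamoxifen, 87.3 with fasting and 11.6 in the combination arm.

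The comparison of the combination with tamoxifen asked what fasting added in treated tumours. Most hypoxia and glycolysis genes and some ribosome biogenesis genes fell, and some interferon-stimulated and insulin withdrawal genes rose. KRT6B, a keratin of activated epidermis that is a close copy of KRT6A, fell by 4.47 ± 0.62 SE on the log2 scale (edgeR adjusted p = 0.00131), and the gap junction gene GJB2 (chromosome 13, 20187463 to 20192938) went from 14.3 ± 10.8 (n = 3) to 1.38 ± 0.406 CPM (SD, n = 6; log2 fold change -3.36 ± 0.41 SE, edgeR adjusted p = 0.000939). The cornified envelope gene SPRR1B fell by 3.72 ± 0.65. DRC7, a part of the motile cilium, rose by 3.53 ± 0.53 and AL121956.7 by 3.90 ± 0.48. In all, 1648 of 15834 genes were called, 835 higher and 813 lower, and 529 of them changed over 2-fold.

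Of 25 hypoxia and glycolysis genes, 17 fell and 0 rose (24 and 0 adjusted over the list alone; median -0.70, camera adjusted p = 2.15e-15, adjusted p = 0.459 with an estimated correlation). Combination libraries 1, 2 and 5 were again lowest, and without them the median of the list hypoxia and glycolysis in TMX+fasting vs TMX was -0.50. BHLHE40 was down by 1.18 ± 0.13, VEGFA by 1.03 ± 0.12 and PGAM1 by 0.59 ± 0.10. Ribosome biogenesis had 10 of 20 genes lower (16 adjusted over the list alone; median -0.39, camera adjusted p = 9.60e-10, adjusted p = 0.459 with an estimated correlation), led by WDR43 at -0.67 ± 0.12, and oxidative phosphorylation 10 of 31 (14 adjusted over the list alone; median -0.23, camera adjusted p = 1.68e-08, adjusted p = 0.459 with an estimated correlation). Ribosomal proteins had a median of -0.22 with 0 of 32 called (18 lower adjusted over the list alone; camera adjusted p = 6.46e-09, adjusted p = 0.459 with an estimated correlation). Cholesterol synthesis had 6 of 24 lower (7 adjusted over the list alone; camera adjusted p = 6.06e-05, adjusted p = 0.459 with an estimated correlation) and the ATF4 stress response 7 of 26 lower and STC2 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.000838, adjusted p = 0.459 with an estimated correlation). DNA replication had 2 of 25 lower, MCM10 and E2F1 (5 adjusted over the list alone; camera adjusted p = 2.28e-07, adjusted p = 0.459 with an estimated correlation), again with combination library 2 lowest. Mitosis genes had a median of -0.40 with 0 of 23 called (0 adjusted over the list alone; camera adjusted p = 3.67e-05, adjusted p = 0.635 with an estimated correlation), again with combination libraries 1 and 2 lowest. Without both the median of the list mitosis in TMX+fasting vs TMX was -0.13 (camera adjusted p = 0.0177).

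Of 24 interferon-stimulated genes, 7 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.80, camera adjusted p = 1.68e-08, adjusted p = 0.459 with an estimated correlation). XAF1 was up by 1.58 ± 0.34 SE, MX1 by 0.95 ± 0.24 and IFI6 by 0.84 ± 0.22. The mean log2 deviation of the interferon list was -1.117 to -0.309 with tamoxifen and -0.709 to 0.73 in the controls. In the combination it was -0.683 (library 2) to 0.711 (library 5), within the range of the controls. Library 2 also lay within the tamoxifen range. The myeloid list had a median of 0.55 (0 of 4 called, 1 higher adjusted over the list alone; camera adjusted p = 0.526), and combination library 5 was the highest of its arm on both lists, at 0.711 for interferon and 0.985 for myeloid genes. CD74 had a log2 fold change of 2.31 ± 0.78 SE (edgeR adjusted p = 0.0724). Of 19 insulin withdrawal genes, 7 rose and BNIP3, also a hypoxia gene, fell (9 and 3 adjusted over the list alone; median 0.46, camera adjusted p = 0.00987, adjusted p = 0.459 with an estimated correlation). FBXO32 was up by 1.07 ± 0.19 and BCL6 by 1.07 ± 0.22. Of 26 glucocorticoid receptor targets, ZBTB16, SGK1 and BIRC3 rose and DDIT4 fell (4 and 3 adjusted over the list alone; median 0.07, camera adjusted p = 0.751). ZBTB16 (chromosome 11, 114059711 to 114256765) went from 0.205 ± 0.226 (n = 3) to 13.3 ± 11.5 CPM (SD, n = 6; log2 fold change 5.90 ± 1.45 SE, edgeR adjusted p = 0.0241), against 3.76 ± 2.86 in control and 46.4 ± 24.0 with fasting (SD, n = 3 each). Of 6 measured keratinocyte genes, KRT5, KRT10 and SBSN fell and KRT15 rose (4 and 1 adjusted over the list alone; median -1.49, camera adjusted p = 0.00635, adjusted p = 0.459 with an estimated correlation). Without tamoxifen library 3 the median of the list keratinocyte in TMX+fasting vs TMX was -0.45. Of 8 histone genes 1, H1-2, rose (4 adjusted over the list alone; camera adjusted p = 0.0143, adjusted p = 0.473 with an estimated correlation), a call lost without tamoxifen library 2. CCND1 fell by 0.63 ± 0.16 and ESR1 had a log2 fold change of 0.47 ± 0.16 (edgeR adjusted p = 0.0673).

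Of 59 named genes called, 18 were called whichever library was left out, while ZBTB16 and CCND1 were lost when any 1 of the 3 tamoxifen libraries was left out, SGK1 without library 1 or 3 of that arm (1.28 to 1.80), and XAF1, MX1 and BCL6 without library 2 or 3. The count of 1648 was 462 without tamoxifen library 2, 274 without tamoxifen library 3, 725 without combination libraries 1 and 2, 2711 with quality weights and 1064 from the libraries of the arms compared.

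The comparison of the combination with fasting asked what tamoxifen added in fasted tumours. Some glucocorticoid receptor targets fell, SGK1 and FKBP5 among them, and several genes near silent with fasting alone rose. SGK1 went from 87.3 ± 15.5 CPM with fasting (n = 3) to 11.6 ± 3.72 CPM in the combination (SD, n = 6; log2 fold change -2.92 ± 0.29 SE, edgeR adjusted p = 4.91e-05). FKBP5, which encodes a co-chaperone of steroid receptors (chromosome 6, 35573585 to 35728583), went from 259 ± 11.7 (n = 3) to 88.0 ± 26.0 CPM (SD, n = 6; log2 fold change -1.56 ± 0.23 SE, edgeR adjusted p = 0.000845). Of the 26 measured targets 10 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.60, camera adjusted p = 1.45e-08, adjusted p = 0.0858 with an estimated correlation), DDIT4 among them by 1.22 ± 0.19. IGHG4 rose by 7.64 ± 0.48 (edgeR adjusted p = 1.09e-06). MPPED1 was at least 262-fold higher, LINC01639 at least 141-fold and CAPSL at least 64.4-fold, and the ratio was 265 for CIBAR2 (95% interval 47.4 to 10500) and 206 for AL121956.7 (36.7 to 8150). In all, 1362 of 15834 genes were called, 685 higher and 677 lower, and 662 of them changed over 2-fold.

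Of 12 progesterone receptor targets, HSD11B2, STAT5A and FKBP5 fell and 0 rose (7 and 1 adjusted over the list alone; median -0.77, camera adjusted p = 0.00454, adjusted p = 0.304 with an estimated correlation). Of 38 oestrogen receptor targets 12 fell and 9 rose (16 and 10 adjusted over the list alone; median -0.40, camera adjusted p = 0.263). SGK3 was down by 1.96 ± 0.21 SE, PKIB down by 1.40 ± 0.16 and SLC9A3R1 up by 1.47 ± 0.13. The insulin withdrawal list had 6 genes lower and TXNIP and RBL2 higher (7 and 2 adjusted over the list alone; median -0.37, camera adjusted p = 0.00902, adjusted p = 0.648 with an estimated correlation), INSR falling by 0.81 ± 0.11. The ATF4 stress response had SLC3A2, ATF5 and DDIT4 lower and STC2 higher of 26 (3 and 1 adjusted over the list alone; camera adjusted p = 0.00477, adjusted p = 0.816 with an estimated correlation). Hypoxia and glycolysis had VEGFA and BHLHE40 lower and ADM higher of 25 (3 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 0.0208, adjusted p = 0.816 with an estimated correlation). Mitosis genes (median -0.35, camera adjusted p = 0.0016), interferon-stimulated genes (-0.18, 0.0263) and ribosomal proteins (-0.10, 0.0226) were lower as lists with 0 members called, each at an adjusted p = 0.816 with an estimated correlation. Cholesterol synthesis (0.11, 0.0409) was higher with DHCR24 up and PCSK9 down, at an adjusted p = 0.816 with an estimated correlation. The preset call was lost for the insulin withdrawal list without fasting library 2, and for cholesterol synthesis in 5 fits with 1 library left out, hypoxia and glycolysis in 4, interferon-stimulated genes in 4 and ribosomal proteins in 4. AR rose by 1.05 ± 0.17, IER3 by 1.28 ± 0.18 and COL5A2 by 2.22 ± 0.44, and EGR3 fell by 1.48 ± 0.29.

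Of 54 named genes called, 28 were called whichever library was left out, SGK1, FKBP5, DDIT4, IGHG4 and AR among them, and the count of 1362 was 698, 831 and 770 without fasting libraries 1, 2 and 3, 3253 with quality weights and 860 from the libraries of the arms compared. Without combination libraries 1 and 2 the mitosis median was -0.05 and that call was lost, and without libraries 1, 2 and 5 the hypoxia and glycolysis median was -0.03 with the test upward.

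**Figure D4:**
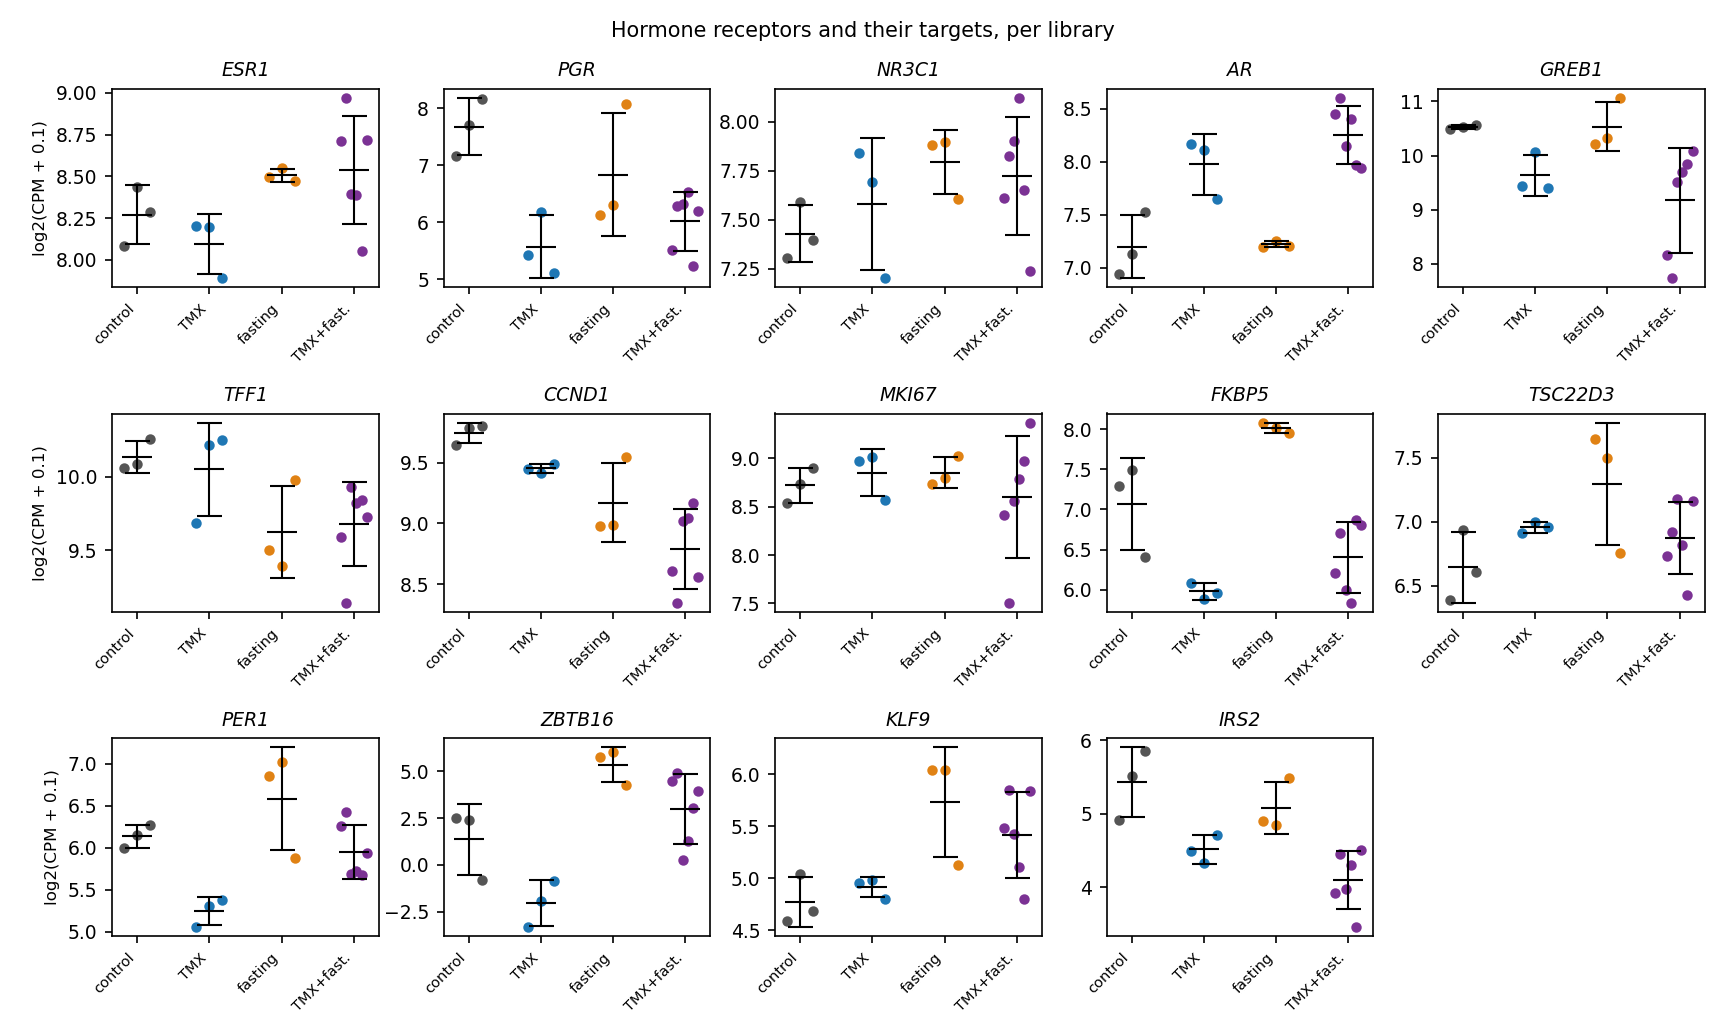
Log2(CPM + 0.1) of the 14 panel genes fixed before the data were examined, 1 panel per gene, with a dot per library by arm and the mean ± SD per arm. FKBP5 averages 140 CPM in control, 63.2 with tamoxifen, 259 with fasting and 88.0 in the combination arm, and ESR1 310, 275, 363 and 380 CPM.

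The interaction asked whether fasting acted differently with and without tamoxifen. No gene was called by edgeR, with a smallest adjusted p of 0.311 and 985 genes at an unadjusted p under 0.05. Limma-voom called 0 genes, DESeq2 called 37 and quality weights gave 125, while edgeR called 22 without fasting library 3 and 1 without combination library 2. FKBP5 had an interaction of -0.41 ± 0.37 SE on the log2 scale, ZBTB16 2.26 ± 2.02 and SGK1 -0.29 ± 0.50, and DDIT4 -1.56 ± 0.29 (edgeR adjusted p = 0.311). With the preset correlation 13 lists passed, the glucocorticoid receptor targets at a median of -0.30 and the oestrogen receptor targets at 0.39, but with an estimated correlation the smallest adjusted p was 0.369.

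Fold changes were compared between comparisons across the 15834 genes, which are not independent replicates. The simulations drew each gene independently, so their ranges of r are too narrow for genes that vary together and do not measure chance. Among replicates 1 to 3, deviations from the arm mean already correlated at -0.217 to 0.216 between libraries of different arms. Fasting against control and the combination against tamoxifen share no library, and their log2 fold changes had r = 0.508, where 20 simulations with no effect gave -0.0266 to 0.0179. Of their called genes 63 were higher in both and 120 lower in both, where independent lists would share 8.91 and 9.81, and 0 were opposite. Tamoxifen against control and the combination against fasting, which also share no library, had r = 0.665 (simulated -0.0256 to 0.0233), with 134 genes higher and 161 lower in both (9.95 and 11.2 for independent lists) and 0 opposite. Tamoxifen and fasting, each against the same controls, had r = 0.33 against a simulated mean of 0.505, and a covariance of 0.0887 against 0.0458 simulated. They shared 17 higher and 6 lower genes (2.45 and 3.17 for independent lists), with 2 opposite. Tamoxifen and the combination against control had r = 0.721 (simulated 0.579) and a covariance of 0.349 against 0.0455. Fasting and the combination against control had r = 0.588 (simulated 0.583) and a covariance of 0.221 against 0.0456. The combination against tamoxifen and against fasting had r = 0.515 (simulated 0.334) and a covariance of 0.196 against 0.0225. The 3 control libraries could not be split into parts of 2 or more, so part of the excess over independent lists may come from shared libraries.

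In the combination against control no cell type list passed by camera. Of the 10 cell type lists, lymphocyte had 1 measured member and erythroid 0, and neither was tested. The fibroblast list had 3 of 10 members higher, COL5A2, COL3A1 and FBN1, and 0 lower (3 and 0 adjusted over the list alone; median 0.06, camera adjusted p = 0.579). COL5A2 went from 22.9 ± 4.35 CPM in control to 74.5 ± 13.0 with tamoxifen (SD, n = 3 each) and 122 ± 54.1 in the combination (SD, n = 6), while the other 7 members did not pass. Endothelial markers had FLT1 and ENG lower of 7 (2 adjusted over the list alone; median 0.08 with the test downward, camera adjusted p = 0.676), smooth muscle and pericyte 0 of 6 (camera adjusted p = 0.931), myeloid 0 of 4 (0.433), adipocyte 0 of 3 (0.883), skeletal muscle MB and NEB higher of 3 (0.312) and keratinocyte KRT15 higher and KRT5, KRT10 and SBSN lower of 6 (0.433), with the camera adjusted p in brackets. Luminal epithelium genes had 5 of 15 higher and 4 lower (median -0.06 with a mean of 0.08, camera adjusted p = 0.883). Mitochondrial transcripts made up 2.31% to 3.56% of counts over the 15 libraries.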

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

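Among the 6 combination libraries, 76 sets of values were tested for a library far from the others, and 4 had one, where chance gives about 1 in 20. The sets were named genes, gene lists, measures of the libraries such as total count, and the first and second principal components. SYNPO2L was at 36.3 CPM in library 6 against 1.47 to 8.46 in the other 5, and SPRR1B at 1.26 CPM in library 6 against 0.0921 to 0.378. IGHG4 was at 97.4 CPM in library 1 against 42.0 to 49.8. The myeloid list, with 4 measured members, had a mean log2 deviation of 0.985 in library 5 against -0.593 to -0.143. No explanation of these 4 values was tested.

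The effect of fasting differed with and without tamoxifen for 13 gene lists by camera with the preset correlation, and for 0 of them with an estimated correlation, where the adjusted p was 0.369 to 0.75. Negative interactions, by median log2 value, were glucocorticoid receptor targets at -0.297 (camera adjusted p = 0.000759), progesterone receptor targets at -0.403 (0.0333), mitosis at -0.381 (4.65e-06), hypoxia and glycolysis at -0.191 (0.000127), ribosomal proteins at -0.0944 (0.00338) and fatty acid oxidation at -0.136 (0.007). Positive interactions were oestrogen receptor targets at 0.393 (5.64e-06), DNA replication at 0.164 (0.0143), cholesterol synthesis at 0.244 (0.000187), fatty acid synthesis at 0.26 (0.0135), the unfolded protein response at 0.154 (0.00162), interferon-stimulated genes at 0.617 (4.76e-05) and ribosome biogenesis at 0.131 (0.0318). Of the 13, 8 passed whichever library was left out. The lists lost in some such fit were progesterone receptor targets (8 libraries), DNA replication (6), fatty acid synthesis (control library 2, tamoxifen library 1), ribosome biogenesis (8) and ribosomal proteins (control library 2). On the oestrogen receptor targets fasting library 3 stood apart, at 0.577 against -0.073 and -0.19 in fasting libraries 1 and 2. On interferon-stimulated genes the controls were at 0.73, 0.276 and -0.709, and on the myeloid list at 1.05, 0.875 and -0.443. Combination libraries 1 and 2 stood apart on mitosis, at -0.761 and -1.24 against -0.03 to 0.307 in the other 13. Without both, a fit chosen after the results had been seen, the median of the list mitosis in interaction of TMX and fasting was -0.105.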

How the results depend on the processing

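The fits without combination libraries 1 and 2, and without 1, 2 and 5, were chosen only after the results had been seen. The genes called by edgeR in the 6 comparisons numbered 493 (tamoxifen against control), 360 (fasting against control), 4276, 1648 and 1362 (combination against control, tamoxifen and fasting) and 0 (interaction). Where an alternative moved a count over 1.5 times, the cause was not tested unless fewer libraries were used.

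With DESeq2 the counts were 858 for tamoxifen, 1031 for fasting and 37 for the interaction. With limma-voom sample weights they were 1369, 3765, 2711 (combination against tamoxifen), 3253 (combination against fasting) and 125 (interaction). From the libraries of the arms compared alone they were 791, 16, 1064 and 860. Without combination libraries 1, 2 and 5 they were 969, 1160, 662 (combination against tamoxifen) and 11 (interaction), and without 1 and 2 they were 683 (fasting) and 725 (combination against tamoxifen). With no low-count filter 2 genes passed in the interaction. Plain limma-voom, DESeq2 size factors, upper-quartile scaling, the strict filter and combination libraries 1 to 3 alone kept all 6 counts within 1.5 times. With upper-quartile scaling 65.1% of the calls with fasting were higher, against 46.9%.

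With 1 library left out at a time, the counts were 181 to 795 for tamoxifen, 2 to 1137 for fasting, 2749 to 4989 for the combination against control, 274 to 2243 against tamoxifen, 698 to 2020 against fasting and 0 to 22 for the interaction (22 without fasting library 3, 1 without combination library 2).

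The replicate numbers did not pair the arms: over 18 pairs of same-number libraries r was -0.217 to 0.19 (median -0.00507), and the best match had its own number in 8 of 36 cases. The fit with the replicate block used combination libraries 1 to 3 alone and tested 15647 genes, with counts of 639, 511, 4577, 2368, 1955 and 0, against 695, 468, 4699, 2272, 2005 and 0 in the same libraries without the block.

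Of the 65 list calls, 2 turned direction in an alternative. Lists that were not called turned as well, up to 11 of 174 list results in an alternative. Interferon-stimulated genes in fasting against control were at 0.146 and, with 1 library left out at a time, at -0.0809 (without control library 3) to 0.483. The list hypoxia and glycolysis in TMX+fasting vs fasting was at -0.265 and, without combination libraries 1, 2 and 5, at a median of -0.0299, still negative, while the camera direction turned upward (adjusted p = 0.895). Fewer libraries were used in both. Of 259 calls of named genes, 28 were lost with limma-voom, 14 with sample weights, 40 with no low-count filter and 0 with DESeq2, and of the 255 that the arms compared alone could give, 54 were lost. Of 65 list calls, 65 were lost with an estimated correlation and 40 with fry. No called gene was called in the opposite direction in any alternative. Depth limits genes under a few counts per library, where folds are ratios with counting intervals.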

Other observations

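The tests against host tissue and against host B or plasma cells below, the list of cilia genes and the fits without combination libraries 1 and 2 or 1, 2 and 5 were chosen only after the results had been seen.

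Genes of motile cilia were higher in the combination arm. Of 49 measured members of the CFAP, DNAH, DNAI, RSPH and TEKT families, 43 were higher and 1 lower in the combination against control, with a median log2 fold change of 2.44 (camera p = 1.65e-21, p = 0.0156 with an estimated correlation). The median was 1.81 against tamoxifen with 38 higher (p = 0.0136 with an estimated correlation), and 1.94 against fasting with 34 higher (p = 0.00572). Tamoxifen alone had 4 higher and a median of 0.516, fasting alone 0 higher by edgeR and a median of 0.451, and the interaction a median of 1.17. By camera with an estimated correlation over the 49 genes, p was 0.187, 0.501 and 0.0343 in turn. The low-count filter worked by arm, so cilia genes near silent elsewhere could be measured through the combination libraries alone. The shares called higher and the camera p-values are therefore partly set by which genes were measured. The mean log2 deviation of the list was 0.709 to 1.62 in the 6 combination libraries and -1.15 to -0.311 in the other 9. A general rise of fibroblast, smooth muscle, endothelial and myeloid marker counts is argued against, since the median of 27 such markers was -0.0253 (95% interval -0.362 to 0.11). That interval came from resampling the 27 genes and does not measure the spread between libraries. Per library their mean log2 deviation was -0.222 to 0.192 in the combination and -0.228 to 0.27 in the controls. How mouse reads were handled is not known, so these counts need not measure mouse tissue. Reads of host ciliated cells need not move those markers, so this test cannot exclude them. In the 6 libraries 4 airway secretory genes had 25 counts, which concerns airway tissue alone. The tables argue against the 3 libraries farthest from the others, since 37 of the 43 genes were still called without libraries 1, 2 and 5. They argue against exon length or mean expression over all libraries. The medians of 10000 random lists matched on both had an upper 95% limit of 0.329. Those lists were not matched on the level in control, so they do not test entry through the filter. Reads of host ciliated cells stay open. Another candidate explanation that stays open is a change in the tumour cells under both treatments, which may be biological and was found and tested on the same data.

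Counts here are totals over 3 control, 3 tamoxifen, 3 fasting and 6 combination libraries, so the combination totals cover more libraries. IGHG4 and its paralogs IGHG1, IGHG3 and IGHE were higher in both tamoxifen arms, with IGHG4 at 21 counts in control, 709 with tamoxifen, 11 with fasting and 3739 in the combination (0.575, 18.7, 0.255 and 54.3 CPM on average). IGHG2 had 2, 17 and 41 counts in control, tamoxifen and the combination. Not all heavy chain genes shared this rise: IGHM had 4 counts in control, 0 with tamoxifen and 4 in the combination, and IGHA1 had 12, 9 and 33. As a test of host B or plasma cells, 8 human light-chain constant genes had 2 counts together (upper 95% limit 7.22) in the combination libraries. That argues only against cells whose light-chain reads match the human genes as well as their heavy-chain reads do. How mouse reads were handled is not known, so the test cannot exclude mouse cells. CD22 went from 83 counts in control to 680 with tamoxifen and 3282 in the combination (2.28, 17.95 and 47.9 CPM on average), and CD19 from 0 to 1 and 48, while CD79A had 7, 8 and 12 counts and MS4A1 0 in each. No explanation of the rise of CD22 and CD19 was tested. The rise of IGHG1, IGHG3 and IGHE was 23.3 ± 2.05% of the IGHG4 rise with tamoxifen (SD, n = 3) and 29.5 ± 8.89% in the combination (SD, n = 6), a difference of 6.19 points (SE 3.82). Among the 3, IGHE had the most counts in the combination (686, against 384 for IGHG3 and 118 for IGHG1). A like fraction in both arms is expected from shared reads and also if these genes rose together. The test therefore cannot tell the 2 apart.

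Fasting library 3 lay near the controls on the first principal component. On the 1648 genes called between the combination and tamoxifen it scored -0.176, outside the -0.523 to -0.371 of the controls and towards fasting libraries 1 and 2 at -0.0306 and 0.0926, which argues against a control labelled as fasting. Its host-marker score differed from the mean of the other pair by -0.234 against a pooled SD of 0.162, so another content of host cells cannot be told apart from a weaker response, with 1 library and a difference between 1 and 2 SD. No biological explanation was tested.

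Other splits of the same libraries were fitted for each comparison. Tamoxifen against control (493 genes, highest other split 0) and fasting against control (360 genes, highest other split 0) have 10 splits each, too few for a share under 0.05, and 1 of them gave as many genes. For the combination against control (4276 genes) and against fasting (1362 genes) only the real split of 84 gave as many. The highest others gave 2095 and 678. Each share is under 0.05, but it bears on chance only if the libraries are independent samples, which the labels do not say. For the combination against tamoxifen 2 of 84 splits gave at least the 1648 genes, a share under 0.05, but the other of them gave more (1906). In those 3 comparisons the highest other split set combination libraries 1, 2 and 6 against the rest, which points to a structure among the combination libraries. For the interaction, 32 of 100 splits gave at least the 985 genes at an unadjusted p under 0.05, with a highest other of 3839. Those splits shuffle the libraries over all 4 arms and carry the effects of both treatments into the interaction, so they decide nothing about chance.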
